A study of Mus musculus with 24 samples.

How the data were processed

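Total RNA from the neural fraction cells of the tumour stroma had been amplified, labelled with biotin and hybridised to Affymetrix mouse arrays whose probe sets use perfect-match probes alone. The deposited values are log2 values made by the authors with RMA (background correction, quantile normalization between arrays and summary per probe set) in the affy package, per the submitters' processing notes, which give no version. The log2 scale was checked on the values, which ran from 3.91 to 13.6 with near-equal medians in all 24 arrays, and no pair of arrays held identical values. Each of the 8 groups, formed by 4 hairpins and 2 diets, had 3 arrays that the series calls technical replicates, and no sample was left out. Whether the 3 arrays of a group came from 1 animal, 1 pool or several animals is not stated.

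Of 45141 probe sets, 28898 had 1 gene symbol in the supplied annotation, 551 had several and 15692 had none. Only those with 1 symbol were used, and 99.28% of these matched the supplied gene table by Entrez identifier. They gave 17097 genes. For the 7180 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. Genes whose probe set had a mean below the 40th percentile of all probe sets, 6.27 on the log2 scale, were left out as dim, which removed 5253 genes and kept 11844. Of 23 control probe sets that the array names for nonspecific binding by GC content, 19 lay below that level. The tumours were human, and possible binding of human transcripts to mouse probe sets was not tested. The values have no count depth, and the number of arrays alone limits their precision.

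Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of the 8 group means over all 24 arrays, with empirical Bayes moderated two-sided tests. The residual degrees of freedom were 16, or 11 with the scan batch as a block, and the prior degrees of freedom were 6.21. P-values were adjusted by the method of Benjamini and Hochberg over the 11844 genes within each comparison, with a threshold of 0.05. The 10 comparisons were the diet effect with each of the 4 hairpins (PA-rich minus control), the difference of that effect between the EGR2 hairpins and PLKO and between shGAL and PLKO, and the EGR2 hairpins or shGAL minus PLKO on each diet. For EGR2, the mean of the 2 hairpins was tested, and each hairpin alone is given beside it. Changes are on the log2 scale with the standard error of the model, and group levels with the standard deviation of 3 arrays.

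The scan batch in the labels went one to one with the replicate number within each hairpin and held both diets. In the residuals of the same hairpin, correlations between same-number arrays of the 2 diets ran from -0.03 to 0.24, with 7 of 12 above 0.1, and the means between other numbers from -0.12 to 0.01. Scan batch was therefore tried as a block, and each hairpin was compared with PLKO in the 1 batch they shared, where each side had 1 array per diet. The named genes were, per comparison, the 12 largest rises and the 12 largest falls past the threshold that had the same sign in each replicate number (in each hairpin for the EGR2 means), every list member past the threshold over all genes or adjusted over the list alone, and Egr2 and Gal. The text gives examples from these genes, preferring those whose calls held in the alternatives, and a choice among them was made after the values were seen.

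The 29 gene lists covered Schwann and glial identity, myelin, the repair Schwann cell programme, neurons, synapses, axon guidance, neurotrophic factors and perineuronal nets. They also covered matrix and its proteases, markers of further cell types, lipid use and synthesis, and stress, immediate early, inflammatory and interferon genes. The cell cycle, hypoxia, oxidative phosphorylation and ribosomal proteins made up the rest. Each list was tested against the other genes with camera in limma (preset correlation between genes of 0.01, adjusted over the 29 lists within a comparison), with an estimated correlation and fry in limma beside it. The median over members, the counts of members past the threshold over all genes and the counts adjusted over the list alone are given. The comparisons, tests, lists, named-gene rule and alternatives were fixed before the data were examined.

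The procedure was tested on simulated data with the group sizes of the study, for the diet effect with PLKO over 11844 genes. Of 100 genes given a change of 0.5 on the log2 scale 85 were called, and of 100 given a change of 1, 99 were called. Of 190 calls in all, 6 were of unchanged genes, and 0 had the wrong sign. With no change simulated 0 genes were called with limma. The 1 shifted list was called and 0 other lists were. The simulated noise was independent between genes and held no batch effect. How the list tests behave under correlation between genes was thus not tested by the simulation.

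The alternatives were the scan batch as a block, no filter on dim probe sets, a filter at the 60th percentile, the mean of all probe sets of a gene, only the arrays of the groups compared, empirical Bayes with trend and robust options, renewed quantile normalization, and leaving out each array in turn. Another background correction was planned only where scanner files were at hand, and since the values used here were already summarised by RMA, it was not run. Each result was also compared with other splits of the same arrays, all 10 for comparisons of 3 arrays with 3 and 100 drawn ones, the real one included, for the others. For these others, splits that exchange whole groups were added after the data were seen, and for the differences of diet effects also splits that exchange the diets within pairs of a shared scan batch.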

Results

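Messenger RNA was measured on mouse expression arrays in the cells that the labels call the neural fraction, taken from the stroma of orthotopic tumours of SCC25, a human oral squamous carcinoma line, grown in immunodeficient NSG mice. The tumour cells carried 1 of 4 short hairpin RNAs: the non-targeting control PLKO, shEGR2_40.9 or shEGR2_38.9 against EGR2, or shGAL against GAL. EGR2 is a transcription factor that drives myelination in Schwann cells, and GAL encodes the neuropeptide galanin. The mice received a control diet or a diet rich in palmitic acid, called the PA-rich diet here. The 8 groups of hairpin and diet held 3 arrays each, 24 in all, and the series names the 3 arrays of a group technical replicates. The p-values therefore measure only the spread between these arrays, and the number of arrays limits the precision of every value. The median array value lay between 6.71 and 6.81 on the log2 scale. Scan batches 1 to 6 held 4 arrays each, always with both diets of a hairpin in the same batch, so that each diet effect within a replicate number is a within-batch value. Lists of genes fixed beforehand were tested as groups, and where 1 count of members is given, the count adjusted over the list alone was the same.

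Replicate 3 of shEGR2_38.9 on the control diet stood apart from the other 23 arrays. Its mean was 7.09, against 7.15 to 7.17 in the others. Its control probe sets for the 3′ end of Gapdh exceeded those for the 5′ end by 0.76 on the log2 scale, against -0.12 to 0.08 in the others. Its mean correlation across genes with the arrays of its own group was 0.978, against 0.987 to 0.997 elsewhere. Principal components of the kept genes carried 35.5%, 14.4% and 9.3% of the variance.

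The silenced genes were in the human tumour cells, whereas the arrays measured mouse RNA, so mouse Egr2 and Gal do not check the silencing. Egr2 was abundant in every group. With PLKO its level was 11.83 ± 0.02 on the control diet and 11.64 ± 0.03 on the PA-rich diet (SD, n = 3). With shGAL it was 11.04 ± 0.07 and 10.9 ± 0.15 (SD, n = 3), and so fell against PLKO by 0.78 on the control diet (adjusted p = 3.59e-05) and by 0.75 on the PA-rich diet (SE 0.11, adjusted p = 5.41e-05). With the EGR2 hairpins on the control diet Egr2 fell by 0.29 against PLKO (SE 0.09, adjusted p = 0.0266), a call that ended with only the arrays compared (adjusted p = 0.14), after renewed quantile normalization (adjusted p = 0.0923) and without shEGR2_38.9 control-diet replicate 1 or 2 (adjusted p = 0.0546 each). The diet gave Egr2 changes of -0.19 with PLKO (adjusted p = 0.561), 0.33 with shEGR2_40.9 (adjusted p = 0.0566), -0.23 with shEGR2_38.9 (adjusted p = 0.141) and -0.15 with shGAL (adjusted p = 0.532), none past the threshold. The value with shEGR2_38.9 became -0.04 without control-diet replicate 3 (adjusted p = 0.799), the array set apart. The other Egr2 probe set had lower levels and gave 10.38 ± 0.22 and 10.47 ± 0.11 (SD, n = 3) with shEGR2_38.9 on the control and PA-rich diets, opposite in sign to the probe set used. In the control-diet group that array was the highest on the probe set used, at 11.96, and the lowest on the other, at 10.14. With PLKO and shEGR2_40.9 on the control diet the other probe set gave 10.95 ± 0.03 and 10.58 ± 0.1 (SD, n = 3). It thus also lay lower with both EGR2 hairpins there, but was not tested on its own. Gal had group means between 6.98 and 7.2 and passed the threshold in none of the 10 comparisons.

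The first question was what the PA-rich diet changed with the non-targeting hairpin. With PLKO, interferon response genes were lower on the PA-rich diet. Serpina3n, a secreted serine protease inhibitor, fell from 10.83 ± 0.06 to 9.77 ± 0.15 (SD, n = 3), a log2 change of -1.06 (SE 0.09, adjusted p = 5.08e-07). Lcn2, an iron-sequestering acute phase protein, changed by -1.25 (SE 0.16, adjusted p = 0.000366), and Dsc1, a desmosomal cadherin gene, by -1.14 (SE 0.2, adjusted p = 0.0034). The largest fall among the named genes was that of Tchh, which encodes trichohyalin of the hair follicle (-1.92, SE 0.27, adjusted p = 0.000559). Among the rises were Rassf4 at 1.23 (SE 0.19, adjusted p = 0.00135), the hyaluronan synthase gene Has2 at 0.74 (SE 0.13, adjusted p = 0.00596) and the phosphatidate phosphatase gene Lpin2 at 0.63 (SE 0.11, adjusted p = 0.00348). The neuronal tubulin gene Tubb3 fell by 0.75 (SE 0.1, adjusted p = 0.00054) and the circadian repressor gene Nr1d2 rose by 0.47 (SE 0.08, adjusted p = 0.00491).

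Of the 15 interferon response genes measured with PLKO, 0 rose and 3 fell, and 6 fell when adjusted over the list alone. The fallers were Ifit1 (-1.09), Ifih1 (-0.90) and Rsad2 (-0.91), and the list was lower on the PA-rich diet with a median of -0.10 (adjusted p = 1.49e-05, and adjusted p = 0.0355 with an estimated correlation). Rsad2 no longer passed with only the arrays compared (adjusted p = 0.0861). The lipid synthesis and cholesterol list was lower too, with a median of -0.16, 0 of 15 members up and 1 down over all genes (adjusted p = 0.00324, but adjusted p = 0.0964 with an estimated correlation). Endoplasmic reticulum stress genes were lower as a list (median -0.04, adjusted p = 0.00435, but adjusted p = 0.165 with an estimated correlation). Of its 20 members 1 fell, Xbp1 at -0.54, and 4 fell when adjusted over the list alone. Cell cycle genes were higher as a list (median 0.13, adjusted p = 0.000245, but adjusted p = 0.349 with an estimated correlation), with 0 of 23 members called over all genes and 2 up when adjusted over the list alone. Oxidative phosphorylation genes were lower as a list (median -0.09, adjusted p = 0.00569, but adjusted p = 0.349 with an estimated correlation), with 0 of 22 members called and 2 down when adjusted over the list alone. Endothelial markers were lower as a list (median -0.19, adjusted p = 0.0354, but adjusted p = 0.698 with an estimated correlation). None of the 15 endothelial members passed the test, and the list medians for replicate numbers 1, 2 and 3 were -0.08, -0.50 and 0.04.

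In all, 140 of 11844 genes passed the threshold for the diet with PLKO, 44 higher and 96 lower. Of these, 10 changed by more than 1 on the log2 scale. The count ran from 56, without PLKO PA-rich replicate 1, to 269, without shEGR2_38.9 control-diet replicate 3.

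**Figure D1:**
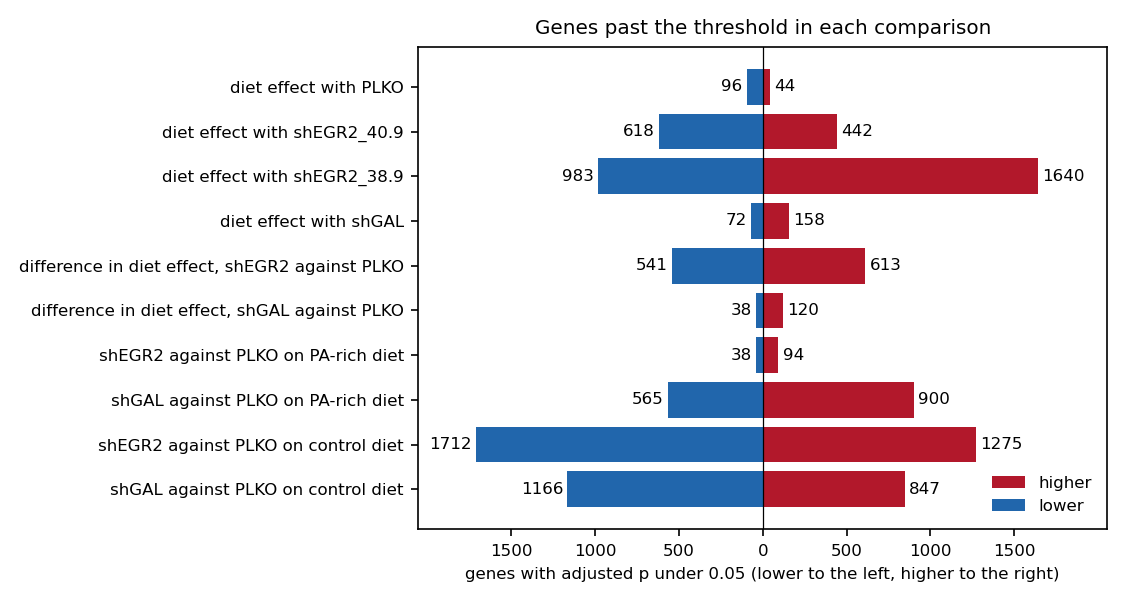
Number of genes past an adjusted p of 0.05 (horizontal axis) in each of the 10 comparisons (vertical axis), with genes lower in the group named to the left of 0 and genes higher to the right. The bars run from 132 genes for shEGR2 against PLKO on the PA-rich diet to 2987 for shEGR2 against PLKO on the control diet.

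With shEGR2_40.9, endothelial markers were lower on the PA-rich diet, and matrix genes were lower with the preset correlation alone (adjusted p = 0.0583 with an estimated correlation). Scn3a, a voltage-gated sodium channel subunit, was at 8.25 ± 0.41 on the control diet and at 5.66 ± 0.17 on the PA-rich diet (SD, n = 3), a change of -2.59 (SE 0.2, adjusted p = 5.08e-08) that ended below the level of 6.27 used as the floor for dim genes. Calcrl, a receptor for adrenomedullin and calcitonin gene-related peptide, changed by -2.52 (SE 0.21, adjusted p = 1.37e-07). Prox1, a transcription factor of lymphatic endothelium, changed by -2.39 (SE 0.33, adjusted p = 4.15e-05), and Flt4, the receptor of lymphatic growth factors, by -2.18 (SE 0.21, adjusted p = 5.17e-07). Ptx3, a secreted pattern recognition protein, had the largest fall (-3.72, SE 0.45, adjusted p = 7.99e-06), although its other probe set had the opposite sign. Calcrl and Ptx3 also ended below the floor, at 5.87 and 5.89, so these folds are not exact. The rises were smaller, with Lgi2 at 1.34 (SE 0.15, adjusted p = 1.97e-06) and Sostdc1, a secreted antagonist of BMP and Wnt signals, at 1.26 (SE 0.11, adjusted p = 3.84e-07).

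Endothelial markers formed the group with the lowest median in shEGR2_40.9, at -1.02. Of 15 members 0 rose and 13 fell, and 15 fell when adjusted over the list alone (adjusted p = 2.21e-20, and adjusted p = 0.0405 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, changed by -1.58, the angiopoietin receptor relative Tie1 by -1.78 and the tight junction gene Cldn5 by -1.02. Matrix genes were lower with a median of -0.88, as 10 of 19 members fell and 14 when adjusted over the list alone (adjusted p = 7.78e-14, but adjusted p = 0.0583 with an estimated correlation). Among them were the basement membrane genes Nid1 (-1.87) and Col4a1 (-1.24) and the fibronectin gene Fn1 (-1.84). Matrix proteases and their inhibitors had 1 member up and 5 of 16 down, or 1 and 8 when adjusted over the list alone (median -0.36, adjusted p = 8.24e-06, but adjusted p = 0.114 with an estimated correlation). The fallers included the inhibitors Timp2 (-1.55) and Timp3 (-1.31). Fibroblast markers were lower as a list, with 2 of 7 down and 3 when adjusted over the list alone (median -0.31, adjusted p = 0.00297, and adjusted p = 0.0444 with an estimated correlation). Of the 17 inflammatory genes 7 fell, and 11 when adjusted over the list alone (median -0.30, adjusted p = 3.29e-07, and adjusted p = 0.0248 with an estimated correlation), among them the chemokine gene Ccl5 (-0.87) and the macrophage growth factor gene Csf1 (-0.54). Of 22 axon guidance genes 4 fell over all genes and 4 when adjusted over the list alone (median -0.09, adjusted p = 0.0215, but adjusted p = 0.0746 with an estimated correlation). They included the guidance cue genes Ntn1 (-1.11) and Sema6a (-0.91).

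Other lists were higher with the diet in shEGR2_40.9. Of 15 lipid synthesis genes 6 rose, and 7 when adjusted over the list alone (median 0.27, adjusted p = 0.000517, and adjusted p = 0.0405 with an estimated correlation), including the fatty acid elongase gene Elovl6 (0.57) the acetyl-CoA carboxylase gene Acaca (0.31) and the sterol synthesis gene Cyp51 (0.39). Cell cycle genes were higher with a median of 0.28, as 10 of 23 rose and 15 when adjusted over the list alone (adjusted p = 3.05e-08, but adjusted p = 0.0603 with an estimated correlation), among them Ccnb2 (0.52) and Birc5 (0.49). Interferon response genes had 3 members up and 1 of 15 down, or 4 and 1 when adjusted over the list alone (median 0.17, adjusted p = 0.0215, but adjusted p = 0.146 with an estimated correlation). The growth cone gene Gap43 fell by 1.83 (SE 0.16, adjusted p = 1.98e-07). In all, 1060 genes passed the threshold, 442 higher and 618 lower, which became 557 and 577 after renewed quantile normalization. Of the 118 that changed by more than 1 on the log2 scale 116 were lower. The count ran from 689, without shEGR2_40.9 PA-rich replicate 2, to 1534, without shEGR2_38.9 control-diet replicate 3, and it was 691 without shEGR2_40.9 PA-rich replicate 3.

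With shEGR2_38.9, 13 of 15 endothelial and 3 of 9 pericyte and smooth muscle markers were lower on the PA-rich diet and 5 of 16 keratinocyte markers were higher. None of these 3 lists passed with an estimated correlation (adjusted p = 0.098, 0.356 and 0.319). Scn3a changed by -2.89 (SE 0.2, adjusted p = 2.35e-09), from 9.44 ± 0.23 to 6.55 ± 0.15 (SD, n = 3). Myh11, the smooth muscle myosin, changed by -2.83 (SE 0.35, adjusted p = 2.99e-06), and Mylk, the myosin light chain kinase, by -2.81 (SE 0.26, adjusted p = 6.22e-08). Krt84, a hard keratin, rose from 9.91 ± 0.51 to 11.93 ± 0.1 (SD, n = 3), by 2.02 (SE 0.18, adjusted p = 3.67e-08). Sdr9c7, an enzyme of the epidermal lipid barrier, rose by 1.83 (SE 0.13, adjusted p = 1.8e-09) and the alarmin cytokine gene Il33 by 1.70 (SE 0.16, adjusted p = 4.86e-08). The control-diet group of this comparison holds the array with the Gapdh end difference of 0.76.

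Of the 15 endothelial markers 13 fell in shEGR2_38.9, and 14 fell and 1 rose when adjusted over the list alone (median -1.31, adjusted p = 1.02e-17, but adjusted p = 0.098 with an estimated correlation). Cdh5 changed by -1.71, Tie1 by -1.92 and Cldn5 by -1.57. Matrix genes had 13 of 19 members down, or 14 when adjusted over the list alone (median -0.82, adjusted p = 1.02e-11, but adjusted p = 0.155 with an estimated correlation). Nid1 changed by -1.87 and Fn1 by -1.52. The matrix medians for replicate numbers 1, 2 and 3 were -1.08, -1.08 and -0.27, the last from the pair with the array set apart. Matrix proteases and inhibitors had 2 of 16 up and 8 down, or 2 and 9 when adjusted over the list alone (median -0.42, adjusted p = 1.46e-05, but adjusted p = 0.184 with an estimated correlation). Timp3 changed by -1.84 and Adam12 by -1.87. Pericyte and smooth muscle markers had 1 of 9 up and 3 down, or 1 and 4 when adjusted over the list alone (median -0.15, adjusted p = 0.0282, but adjusted p = 0.356 with an estimated correlation), Acta2 among the fallers at -0.52. Of 8 macrophage markers 3 fell (median -0.04, adjusted p = 0.00746, but adjusted p = 0.098 with an estimated correlation): the mannose receptor gene Mrc1 (-2.26), Cd68 (-0.50) and the endotoxin co-receptor gene Cd14 (-0.73).

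Keratinocyte markers in shEGR2_38.9 had 5 of 16 members up, or 6 when adjusted over the list alone, and 0 down (median 0.18, adjusted p = 0.0102, but adjusted p = 0.319 with an estimated correlation). They included Krt4 (1.10), Krt6b (1.37) and the cornified envelope gene Sprr1a (0.92). Hypoxia and glycolysis genes had 7 of 18 members up and 0 down, also when adjusted over the list alone (median 0.14, adjusted p = 0.0493, but adjusted p = 0.319 with an estimated correlation), including Egln3 (0.86) and Bnip3 (0.57). The keratinocyte medians for replicate numbers 1, 2 and 3 were 0.06, 0.07 and 0.41, and the hypoxia medians were 0.11, 0.13 and 0.34, so that in both lists the pair with the array set apart lay highest. Lipid synthesis genes had 7 of 15 members up and 1 down, or 10 and 2 when adjusted over the list alone (median 0.33, adjusted p = 0.0161, but adjusted p = 0.155 with an estimated correlation). The rises included the sterol synthesis genes Sqle (0.73) and Mvd (0.51), and the faller was the sterol sensor gene Insig1 (-0.83). Interferon response genes had 2 of 15 up and 4 down, or 3 and 5 when adjusted over the list alone (median -0.16, adjusted p = 0.0282, but adjusted p = 0.244 with an estimated correlation). Rsad2 changed by -1.59 and Oasl2 by 0.67. Endoplasmic reticulum stress genes had 1 of 20 up, Asns at 0.35, and 3 down, or 1 and 4 when adjusted over the list alone (median -0.07, adjusted p = 0.0282, but adjusted p = 0.244 with an estimated correlation). Chac1 changed by -1.30. In all, 2623 genes passed the threshold, 1640 higher and 983 lower. Of the 265 that changed by more than 1 on the log2 scale 223 were lower. Without replicate 3 of the control-diet group the count was 2266, with 1234 higher and 1032 lower, and with only the arrays compared it was 1295, with 634 higher and 661 lower, so the excess of higher genes was not kept there.

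The EGR2 hairpins share no array, and their diet effects were compared across genes, which are not independent replicates. Of the genes called in both, 167 were higher with each hairpin, where 61.2 would be expected from the counts alone, 429 were lower with each (51.3 expected), and 40 had opposite signs (122 expected). The expected counts take calls as independent, whereas the fit shares the spread of each gene between comparisons, which can raise overlaps. The correlation of the log2 changes across all 11844 genes was 0.61. The correlation of the PLKO diet effect with those of shEGR2_40.9, shEGR2_38.9 and shGAL was 0.20, 0.07 and -0.07. Scn3a, Mrc1, Calcrl and Reln were among the largest falls with each EGR2 hairpin. Reln, which encodes the secreted protein reelin, changed by -2.15 with shEGR2_40.9 and -2.30 with shEGR2_38.9. Lgi2 was among the largest rises with each at 1.34 and 1.4.

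**Figure D2:**
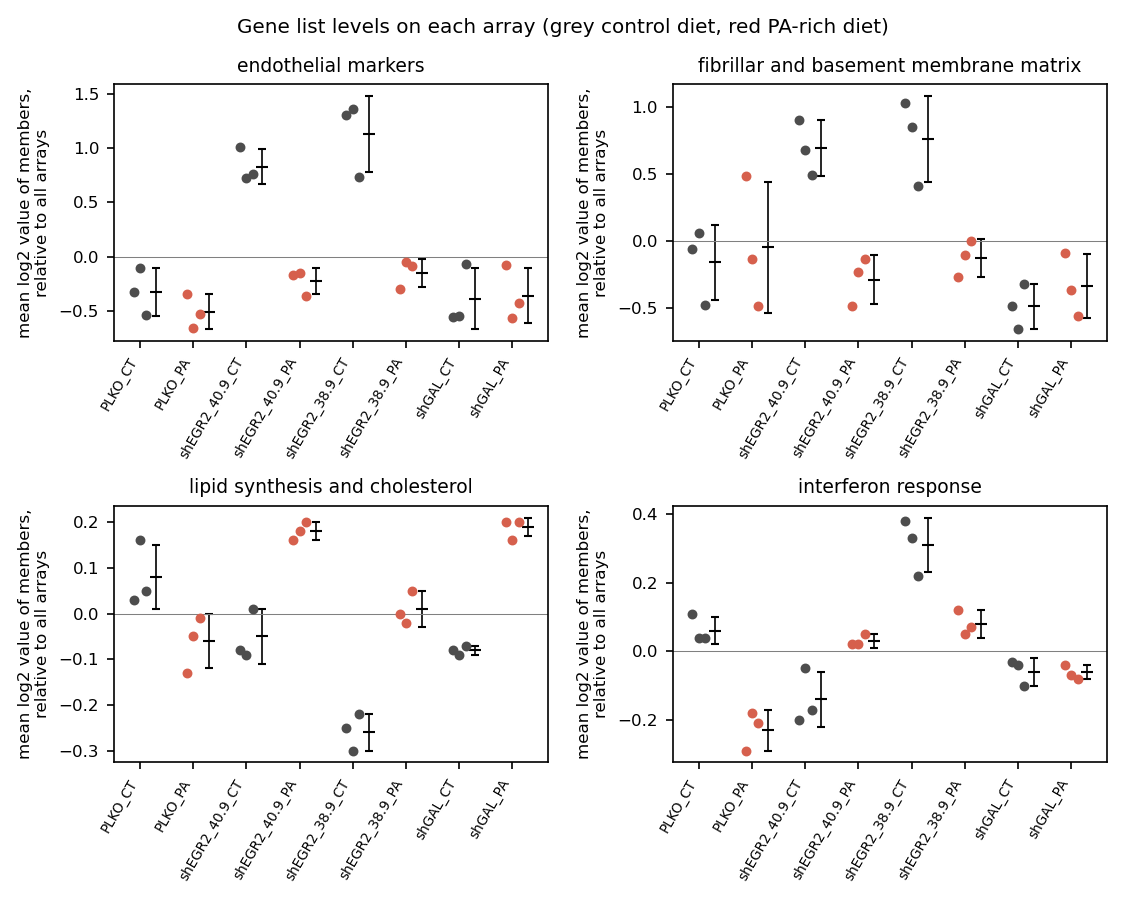
Mean log2 level of the members of 4 gene lists, relative to their mean over all 24 arrays (vertical axis), in each hairpin and diet group (horizontal axis), with a dot per array, grey for the control diet and red for the PA-rich diet, and bars for the mean ± SD of 3 arrays. The endothelial list lay at 0.83 ± 0.16 with shEGR2_40.9 and 1.13 ± 0.35 with shEGR2_38.9 on the control diet, and between -0.51 and -0.15 in the other 6 groups.

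With shGAL, lipid synthesis genes and a pair of alarm cytokines were higher on the PA-rich diet. Il33 rose from 8.34 ± 0.32 to 9.63 ± 0.26 (SD, n = 3), by 1.29 (SE 0.16, adjusted p = 0.000119), and Il18 rose by 0.85 (SE 0.15, adjusted p = 0.00354). Calcb, which encodes a calcitonin gene-related peptide of sensory neurons, rose from 8.53 ± 0.1 to 9.44 ± 0.06 (SD, n = 3), by 0.91 (SE 0.13, adjusted p = 0.000781). The haem oxygenase gene Hmox1 changed by -0.82 (SE 0.09, adjusted p = 4.89e-05), the netrin receptor gene Unc5c by -0.66 (SE 0.08, adjusted p = 0.000119) and the Notch ligand gene Dll1 by -0.67 (SE 0.09, adjusted p = 0.000357). Of 15 lipid synthesis genes 5 rose and 0 fell, and 6 rose when adjusted over the list alone (median 0.27, adjusted p = 1.41e-06, and adjusted p = 0.00765 with an estimated correlation). Idi1 rose by 0.83 and Sqle by 0.57, and outside the list the sterol carrier gene Stard4 rose by 0.92.

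The other lists called for the diet with shGAL were lost with an estimated correlation. Cell cycle genes were higher with 2 of 23 members up, or 7 when adjusted over the list alone (median 0.17, adjusted p = 1.41e-06, but adjusted p = 0.215 with an estimated correlation), Rrm2 at 0.46 among them. Inflammatory genes were higher with 0 of 17 members called over all genes and 4 up when adjusted over the list alone (median 0.11, adjusted p = 0.00506, but adjusted p = 0.215 with an estimated correlation). Matrix proteases and inhibitors were higher with 0 of 16 called and 2 up when adjusted over the list alone (median 0.23, adjusted p = 0.0191, but adjusted p = 0.516 with an estimated correlation). Immediate early genes were lower with 3 of 21 down, Arc at -0.41, Junb at -0.60 and Nr4a1 at -0.38 (median -0.11, adjusted p = 0.00114, but adjusted p = 0.309 with an estimated correlation). Neuronal genes were lower with 1 of 11 down, the gamma-synuclein gene Sncg at -0.64 (median -0.11, adjusted p = 0.00792, but adjusted p = 0.309 with an estimated correlation). With only the arrays compared, Rrm2 (adjusted p = 0.0876), Arc (adjusted p = 0.162), Junb (adjusted p = 0.164), Nr4a1 (adjusted p = 0.0876) and Sncg (adjusted p = 0.0708) no longer passed. Without shGAL control-diet replicate 2 the same held for Arc, Junb and Nr4a1 (adjusted p = 0.197, 0.252 and 0.0692), and Arc and Junb also missed the threshold without shGAL control-diet replicate 1 or PA-rich replicate 1 or 3, at adjusted p from 0.0564 to 0.238. In all, 230 genes passed the threshold, 158 higher and 72 lower, a share of 68.7% higher that became 56.3% after renewed quantile normalization. The count ran from 59, without shGAL control-diet replicate 2, to 528, without shEGR2_38.9 control-diet replicate 3, and it was 47 with only the arrays compared.

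Whether EGR2 silencing in the tumour cells altered the diet effect was tested as the difference between the mean diet effect of both EGR2 hairpins and that of PLKO. The diet effect on endothelial and matrix genes was lower with the EGR2 hairpins, although neither list passed with an estimated correlation (adjusted p = 0.072 and 0.0582). Galnt15, a glycosyltransferase gene, differed by -2.71 (SE 0.34, adjusted p = 2.71e-05) and Gap43 by -1.71 (SE 0.2, adjusted p = 7.08e-06). Angpt2, a vascular growth factor gene, differed by -1.77 (SE 0.22). In the other direction, Lgi2 differed by 1.94 (SE 0.18, adjusted p = 8.88e-07), Sdr9c7 by 1.63 (SE 0.15, adjusted p = 1.09e-06), the hair keratin regulator gene Hoxc13 by 1.5 (SE 0.17, adjusted p = 7.79e-06) and the circadian gene Per2 by 1.29 (SE 0.13, adjusted p = 1.7e-06).

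The difference was negative for 13 of 15 endothelial markers (median -1.05, adjusted p = 1.67e-15, but adjusted p = 0.072 with an estimated correlation). Cdh5 differed by -1.36, Cldn5 by -1.05 and Pecam1 by -1.4. It was negative for 10 of 19 matrix genes, or 17 when adjusted over the list alone (median -0.84, adjusted p = 6.91e-16, but adjusted p = 0.0582 with an estimated correlation). Nid1 differed by -1.54 and Col6a1 by -1.51. It was negative for 7 of 16 matrix proteases and inhibitors, or 10 when adjusted over the list alone (median -0.54, adjusted p = 8.42e-08, but adjusted p = 0.072 with an estimated correlation). Timp2 differed by -1.42 and Mmp13 by -1.62. Of 8 macrophage markers 3 had a negative difference, Mrc1 at -1.61 and Cd14 at -0.65 among them (median -0.16, adjusted p = 0.00494, but adjusted p = 0.0582 with an estimated correlation). Of 22 axon guidance genes 1 had a positive and 5 a negative difference, or 3 and 6 when adjusted over the list alone (median -0.11, adjusted p = 0.0266, but adjusted p = 0.085 with an estimated correlation). Lipid synthesis genes had 7 of 15 positive and 0 negative differences, or 10 and 1 when adjusted over the list alone (median 0.44, adjusted p = 3.6e-06, and adjusted p = 0.0138 with an estimated correlation). Idi1 differed by 0.88, the desaturase gene Scd1 by 0.75 and Dhcr7 by 0.75. Interferon response genes had 5 of 15 positive differences, or 6 and 1 negative when adjusted over the list alone (median 0.10, adjusted p = 0.0398, but adjusted p = 0.209 with an estimated correlation and adjusted p = 0.0772 with the scan batch in the fit). Ifit1 differed by 1.09 and Ifih1 by 0.93. Oxidative phosphorylation genes had 1 of 22 positive, Ndufa4 at 0.53, or 5 when adjusted over the list alone (median 0.18, adjusted p = 0.000474, but adjusted p = 0.178 with an estimated correlation). In all, 1154 genes passed the threshold, 613 with a higher and 541 with a lower diet effect. The majority was not stable: it turned to 574 higher and 599 lower after renewed quantile normalization, to 422 and 497 without PLKO control-diet replicate 2, and to 369 and 402 without PLKO PA-rich replicate 1. Alone, shEGR2_40.9 gave 493 genes, 213 higher and 280 lower, and shEGR2_38.9 gave 1582, 928 higher and 654 lower.

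The same test for GAL compared the diet effect with shGAL with that of PLKO. GAL was targeted by 1 hairpin only. In every comparison with shGAL, an effect of GAL loss therefore cannot be told apart from other effects of that hairpin or its tumours. Positive differences included Tchh at 2.46 (SE 0.38, adjusted p = 0.00113), Acod1, which makes itaconate in activated macrophages, at 1.98 (SE 0.38, adjusted p = 0.00738), Lcn2 at 1.84 (SE 0.23, adjusted p = 0.000183) and Ifih1 at 1.53 (SE 0.14, adjusted p = 4.18e-06). These 4 genes had fallen with the diet in PLKO, a fall that is part of the difference. Il33 differed by 1.73 (SE 0.22, adjusted p = 0.000183). Negative differences included Rassf4 at -1.29 (SE 0.27, adjusted p = 0.0152), Hmox1 at -0.88 (SE 0.13, adjusted p = 0.000814), and the fatty acid oxidation genes Decr1 at -0.77 (SE 0.12, adjusted p = 0.00105) and Cpt1a at -0.76 (SE 0.15, adjusted p = 0.00865). Lipid synthesis genes had 3 of 15 positive differences, or 10 when adjusted over the list alone (median 0.47, adjusted p = 2.15e-08, and adjusted p = 0.00188 with an estimated correlation). Idi1 differed by 1.17. Endoplasmic reticulum stress genes had 3 of 20 positive, or 4 and 1 negative when adjusted over the list alone (median 0.16, adjusted p = 0.00165, but adjusted p = 0.124 with an estimated correlation). Xbp1 differed by 0.62. Inflammatory genes had 2 of 17 positive, or 3 when adjusted over the list alone, Lcn2 among them (median 0.30, adjusted p = 0.00435, but adjusted p = 0.179 with an estimated correlation).

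The remaining lists called for the shGAL difference were lost with an estimated correlation, and all but the last of them also with the scan batch in the fit. Interferon response genes had 3 of 15 positive differences, or 4 and 1 negative when adjusted over the list alone, with a median of 0 and a mean of 0.29, and the members called were Ifih1 (1.53), Ifit1 (1.4) and Rsad2 (1.2) (adjusted p = 0.0399, but adjusted p = 0.327 with an estimated correlation and adjusted p = 0.0575 with the scan batch). Immediate early genes had 1 of 21 negative, Arc at -0.66 (adjusted p = 0.0517 with only the arrays compared), or 2 when adjusted over the list alone (median -0.08, adjusted p = 0.0399, but adjusted p = 0.565 with an estimated correlation and adjusted p = 0.0552 with the scan batch). Synapse genes had 0 of 7 called (median -0.17, adjusted p = 0.0399, but adjusted p = 0.458 with an estimated correlation and adjusted p = 0.0552 with the scan batch). Axon guidance genes had 1 of 22 positive and 1 negative, or 1 and 6 when adjusted over the list alone (median -0.05, adjusted p = 0.0479, but adjusted p = 0.207 with an estimated correlation and adjusted p = 0.061 with the scan batch). Oxidative phosphorylation genes had 0 of 22 called (median 0.13, adjusted p = 0.0227, but adjusted p = 0.458 with an estimated correlation). In all, 158 genes passed the threshold, 120 positive and 38 negative, and the share of positive differences went from 75.9% to 64.7% after renewed quantile normalization. The count ran from 82, without shGAL control-diet replicate 2, to 343, without shEGR2_38.9 control-diet replicate 3.

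On the PA-rich diet, the question was how tumours with silenced EGR2 differed from PLKO tumours (6 arrays against 3). Interferon and cell cycle genes were higher with the EGR2 hairpins. This comparison shares the PLKO PA-rich arrays with the diet effect with PLKO, so opposite signs of the same genes there are not independent. Relative to all arrays, the interferon list lay at -0.23 with PLKO on the PA-rich diet and at 0.06 on the control diet. With shEGR2_40.9 and shEGR2_38.9 on the PA-rich diet it lay at 0.03 and 0.08. The antiviral gene Rsad2 was higher by 0.92 (SE 0.13, adjusted p = 0.000585), Usp18, a brake on interferon signalling, by 0.72 (SE 0.11, adjusted p = 0.000998) and the matricellular gene Ccn4 by 0.68 (SE 0.08, adjusted p = 9.52e-05). Has2 was lower, at -0.81 (SE 0.12, adjusted p = 0.000709), as were the cholesterol hydroxylase gene Ch25h at -0.75 (SE 0.08, adjusted p = 9.52e-05), Nr1d2 at -0.52 (SE 0.07, adjusted p = 0.000585) and the chemokine gene Ccl20 at -0.50 (SE 0.07, adjusted p = 0.000585). Of 15 interferon response genes 4 were higher, or 6 when adjusted over the list alone (median 0.22, adjusted p = 5.06e-09, and adjusted p = 0.00466 with an estimated correlation). Rsad2 and Usp18 were among them, as was Oas2 at 0.40, which missed the threshold with the scan batch in the fit (adjusted p = 0.0574) and without PLKO PA-rich replicate 1 (adjusted p = 0.0958). Cell cycle genes had 2 of 23 members up, Ccnb2 at 0.48 among them, or 12 when adjusted over the list alone (median 0.23, adjusted p = 1.15e-10, and adjusted p = 0.044 with an estimated correlation). Lipid synthesis genes had 0 of 15 called over all genes and 2 up when adjusted over the list alone (median 0.16, adjusted p = 2e-05, and adjusted p = 0.0115 with an estimated correlation).

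Endothelial markers were higher as a list on the PA-rich diet with the EGR2 hairpins, with 0 of 15 called over all genes and 3 up when adjusted over the list alone (median 0.30, adjusted p = 3.2e-05, but adjusted p = 0.372 with an estimated correlation). Inflammatory genes were lower as a list with 0 of 17 called, or 1 up and 4 down when adjusted over the list alone (median -0.12, adjusted p = 0.00192, but adjusted p = 0.118 with an estimated correlation). Immediate early genes were lower as a list with 0 of 21 called (median -0.06, adjusted p = 0.00421, but adjusted p = 0.372 with an estimated correlation). Between arrays of a shared scan batch, the medians with shEGR2_40.9 and shEGR2_38.9 were 0.23 and 0.18 for the interferon list, 0.28 and 0.21 for the cell cycle and 0.28 and 0.02 for lipid synthesis. They were 0.19 and 0.68 for endothelial markers, -0.21 and -0.01 for inflammatory genes and -0.06 and -0.08 for immediate early genes. In all, 132 genes passed the threshold, 94 higher and 38 lower. With the scan batch in the fit the count was 71, with 49 higher and 22 lower, and 57 genes were called both ways. With only the arrays compared it was 595, with 401 higher and 194 lower. Alone, shEGR2_40.9 gave 476 genes and shEGR2_38.9 gave 74. Leaving out 1 array gave counts from 59, without PLKO PA-rich replicate 1, to 257, without shEGR2_38.9 control-diet replicate 3.

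With shGAL on the PA-rich diet, a glutamate transporter, cytokines and a neuropeptide were higher than with PLKO. This comparison shares its arrays with the diet effects with PLKO and shGAL, so the changes of the same genes there are not independent. Slc1a1, the transporter, was at 8.37 ± 0.16 against 5.69 ± 0.09 with PLKO (SD, n = 3), higher by 2.68 (SE 0.23, adjusted p = 4.24e-08), with the PLKO level below the floor of 6.27. Acod1 was higher by 2.32 (SE 0.27, adjusted p = 2.85e-06), the collagenase gene Mmp13 by 2.02 (SE 0.25, adjusted p = 6.67e-06), Il33 by 1.97 (SE 0.16, adjusted p = 1.79e-08) and Calcb by 1.79 (SE 0.13, adjusted p = 7.3e-09). Sostdc1 was lower, at -1.18 (SE 0.11, adjusted p = 3.11e-07), as was the stem cell transcription factor gene Sox2 at -1.11 (SE 0.13, adjusted p = 5.2e-06), which with shGAL lay at 6.25, below the floor. Of 21 immediate early genes 10 fell and 0 rose (median -0.19, adjusted p = 7.06e-08, but adjusted p = 0.0629 with an estimated correlation). Klf2 differed by -0.84, Junb by -0.84 and Nr4a1 by -0.71. Of 17 inflammatory genes 6 rose, or 8 when adjusted over the list alone (median 0.11, adjusted p = 0.000279, but adjusted p = 0.0629 with an estimated correlation). Lcn2 differed by 1.53 and Ccl5 by 0.98. Of 15 lipid synthesis genes 5 rose (median 0.20, adjusted p = 0.000246, but adjusted p = 0.0519 with an estimated correlation). Sqle differed by 0.77 and Mvd by 0.55.

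Matrix proteases and inhibitors had 4 of 16 members up with shGAL on the PA-rich diet, or 5 when adjusted over the list alone, Mmp13 and Mmp10 (0.86) among them (median 0.23, adjusted p = 0.0147, but adjusted p = 0.66 with an estimated correlation). Cell cycle genes had 5 of 23 down (median -0.19, adjusted p = 0.000535, but adjusted p = 0.453 with an estimated correlation). Ccna2 differed by -0.29, a call lost without PLKO PA-rich replicate 1 (adjusted p = 0.0709). Between arrays of the shared scan batch the medians were -0.23 for immediate early genes, 0.14 for inflammatory genes, 0.08 for lipid synthesis, 0.18 for proteases and -0.21 for the cell cycle. In all, 1465 genes passed the threshold, 900 higher and 565 lower. The count was 968 without PLKO PA-rich replicate 3.

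On the control diet, 14 of 15 endothelial, 15 of 19 matrix and 4 of 9 pericyte and smooth muscle genes were higher with EGR2 silencing than with PLKO (6 arrays against 3). None of these 3 lists passed with an estimated correlation (adjusted p = 0.129, 0.129 and 0.44). This comparison shares its control-diet shEGR2 arrays with the diet effects of those hairpins, so the opposite signs of the same genes there are not independent. Galnt15 was higher by 3.00 (SE 0.24, adjusted p = 1.05e-08), Scn3a by 2.85 (SE 0.18, adjusted p = 2.46e-10), Angpt2 by 2.06 (SE 0.16, adjusted p = 4.86e-09) and Gap43 by 1.75 (SE 0.14, adjusted p = 7.74e-09). Scn3a was at 6.00 ± 0.39 with PLKO (SD, n = 3), below the floor of 6.27. Lgi2 was lower, at -1.61 (SE 0.13, adjusted p = 7.04e-09), as was Ccl20 at -1.11 (SE 0.07, adjusted p = 2.46e-10). Cdh5 was at 10.07 ± 0.18 with PLKO, 11.38 ± 0.15 with shEGR2_40.9 and 12.07 ± 0.07 with shEGR2_38.9 (SD, n = 3).

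Of 15 endothelial markers 14 were higher on the control diet and 0 lower (median 1.35, adjusted p = 2.29e-19, but adjusted p = 0.129 with an estimated correlation). Cdh5 differed by 1.65, Tie1 by 1.75 and Cldn5 by 1.22. Of 19 matrix genes 15 were higher (median 0.71, adjusted p = 1.32e-12, but adjusted p = 0.129 with an estimated correlation). Nid1 differed by 1.54 and Col4a1 by 1.16. Matrix proteases and inhibitors had 11 of 16 higher and 1 lower, or 11 and 2 when adjusted over the list alone (median 0.47, adjusted p = 1.19e-07, but adjusted p = 0.129 with an estimated correlation). Timp3 differed by 1.59 and Plau by -0.50. Pericyte markers had 4 of 9 higher and 1 lower (median 0.13, adjusted p = 0.0359, but adjusted p = 0.44 with an estimated correlation). Myh11 differed by 1.79 and Ndufa4l2 by -0.47. Axon guidance genes had 6 of 22 higher and 2 lower, or 7 and 3 when adjusted over the list alone (median 0.12, adjusted p = 0.0359, but adjusted p = 0.134 with an estimated correlation). Ntn1 differed by 1.04, Sema6a by 0.80 and Efna5 by -0.35. Cell cycle genes had 9 of 23 higher and 1 lower, or 10 and 1 when adjusted over the list alone (median 0.20, adjusted p = 7.52e-05, but adjusted p = 0.218 with an estimated correlation). Cenpe, a kinetochore gene, differed by 0.76 and Cenpf by 0.59.

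Lipid synthesis genes had 7 of 15 members lower and 1 higher with the EGR2 hairpins on the control diet, or 9 and 1 when adjusted over the list alone (median -0.25, adjusted p = 0.0185, but adjusted p = 0.134 with an estimated correlation). Idi1 differed by -0.65 and Insig1 by 0.65. Oxidative phosphorylation genes had 8 of 22 lower, or 10 when adjusted over the list alone (median -0.17, adjusted p = 0.00325, but adjusted p = 0.261 with an estimated correlation). Ndufa4 differed by -0.47. Between arrays of a shared scan batch, the medians with shEGR2_40.9 and shEGR2_38.9 were 1.34 and 1.67 for endothelial markers, 1.02 and 0.72 for matrix genes and 0.43 and 0.67 for matrix proteases. They were 0.28 and 0.13 for pericyte markers, 0.11 and 0.11 for axon guidance and 0.28 and 0.11 for the cell cycle. For lipid synthesis they were -0.11 and -0.49, and for oxidative phosphorylation -0.10 and -0.19. In all, 2987 genes passed the threshold, 1275 higher and 1712 lower. Of the 193 that differed by more than 1 on the log2 scale 184 were higher. Alone, shEGR2_40.9 gave 1436 genes, 851 higher and 585 lower, and shEGR2_38.9 gave 3595, 1331 higher and 2264 lower. With only the arrays compared the count was 1550, with 858 higher and 692 lower, and without PLKO control-diet replicate 2 it was 2144, with 1101 higher and 1043 lower, so the excess of lower genes was not kept in these settings.

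With shGAL on the control diet, Mmp13 was at 9.81 ± 0.25 against 7.13 ± 0.45 with PLKO (SD, n = 3), higher by 2.68 (SE 0.25, adjusted p = 1.86e-07). Hmox1 was higher by 1.46 (SE 0.09, adjusted p = 3.92e-10), the orphan receptor gene Gprc5a by 1.46 (SE 0.08, adjusted p = 8.11e-11) and the cytokine gene Il24 by 1.80 (SE 0.22). The prostaglandin-degrading enzyme gene Hpgd was lower, at -1.56 (SE 0.14, adjusted p = 1.86e-07), as were Sox2 at -1.33 (SE 0.13, adjusted p = 4.48e-07, to 6.15 and so below the floor), Pappa at -1.21 (SE 0.09, adjusted p = 1.81e-08) and Per2 at -1.10 (SE 0.11). Of 23 cell cycle genes 10 fell and 0 rose, or 11 when adjusted over the list alone (median -0.26, adjusted p = 0.000203, but adjusted p = 0.363 with an estimated correlation). Mcm6 differed by -0.66 and Rrm2 by -0.64. Of 22 oxidative phosphorylation genes 9 fell and 0 rose, or 11 when adjusted over the list alone (median -0.19, adjusted p = 0.0011, but adjusted p = 0.363 with an estimated correlation). Sdhb differed by -0.36. Of 21 immediate early genes 8 fell and 1 rose, or 9 and 1 when adjusted over the list alone (median -0.12, adjusted p = 0.00566, but adjusted p = 0.363 with an estimated correlation). Klf2 differed by -1.02 and Arc by 0.56. Of 20 endoplasmic reticulum stress genes 4 fell, or 6 when adjusted over the list alone (median -0.13, adjusted p = 0.0157, but adjusted p = 0.363 with an estimated correlation). Sdf2l1 differed by -0.38. The within-batch medians were -0.38, -0.17, -0.16 and -0.11 in that order. In all, 2013 genes passed the threshold, 847 higher and 1166 lower. With only the arrays compared the count was 1202. This comparison shares its arrays with the diet effects with PLKO and shGAL, so the changes of the same genes there are not independent.

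**Figure D3:**
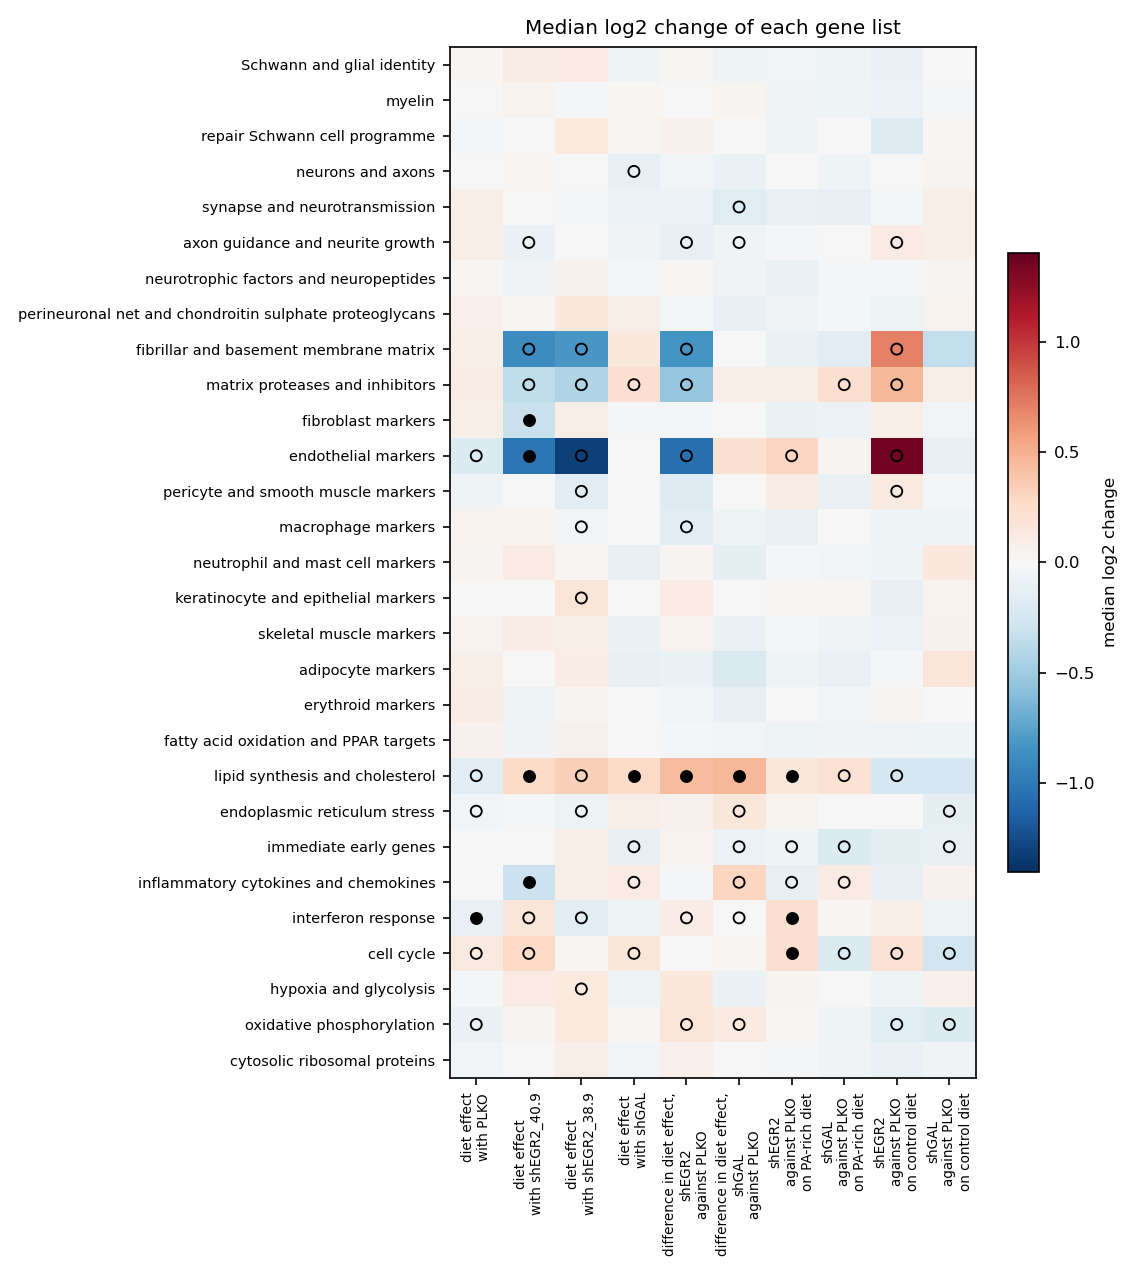
Median log2 change of the measured members of each of the 29 gene lists (vertical axis) in each of the 10 comparisons (horizontal axis), on a colour scale from lower to higher. An open circle marks a list past an adjusted p of 0.05 with the preset correlation and a filled one a list that also passed with an estimated correlation, 70 and 11 of the 290 tests.

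The lists of glial and neural support genes passed the threshold in none of the 10 comparisons. Some of their genes with a probe set were left out as dim, so the tests do not cover them. These were 5 of 18 for Schwann and glial identity, 7 of 16 for myelin and 6 of 19 for the repair Schwann cell programme. For neurotrophic factors they were 7 of 19 and for perineuronal nets 5 of 18. For Schwann and glial identity, with 13 genes measured, medians lay between -0.09 and 0.12 and the lowest adjusted p was 0.257. For myelin, with 9 genes measured, medians lay between -0.08 and 0.05 (lowest adjusted p = 0.334), and for the repair Schwann cell programme, with 13 genes, between -0.18 and 0.14 (lowest adjusted p = 0.171). For neurotrophic factors and neuropeptides, with 12 genes, they lay between -0.09 and 0.06 (lowest adjusted p = 0.171), and for perineuronal net and chondroitin sulphate proteoglycans, with 13 genes, between -0.11 and 0.15 (lowest adjusted p = 0.0945). Single members passed nevertheless, such as Has2 with PLKO and Sox2 with shGAL. Over the 10 comparisons, which share arrays, calls of members numbered 9 higher and 10 lower for Schwann and glial identity. They numbered 5 and 6 for myelin, 12 and 11 for the repair programme, 6 and 5 for neurotrophic factors and 16 and 11 for perineuronal nets. The list test looks for a shift in 1 direction, so members that move both ways can escape it. Among the remaining lists never past the threshold, the lowest adjusted p was 0.101 for fatty acid oxidation and PPAR targets, 0.0885 for cytosolic ribosomal proteins, 0.118 for neutrophil and mast cell markers, 0.105 for skeletal muscle, 0.22 for adipocyte and 0.112 for erythroid markers. The sign of a list's median, mean or test differed in 68 of the 290 tests, and 1 of these was called, the interferon list in the shGAL difference.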

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

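The tests of a lower share of epithelial cells, of the scan batch, of carry-over in the preparation and of splits that keep pairs or groups whole were chosen after the result was seen. The diet effect differed between the EGR2 hairpins and PLKO in 1154 genes and between shGAL and PLKO in 158 genes, each by a test of the difference itself. For EGR2, 1 of 100 drawn splits of the arrays was as large, the real one, with 218 as the highest of the others. Of the 256 splits that exchange the diets only within pairs of a shared scan batch, 100 were tried. Of these 1 was as large, the real one, and the highest other was 678. This excludes chance in the grouping of single arrays. Since such splits mix arrays of different groups, they do not exclude chance between whole groups. The exchange of the diets in both EGR2 hairpins whole, which was not among those tried, gave 1054, near the real count, which points to the structure of the diet groups. For GAL, 2 of 100 drawn splits were as large, and 2 of the 32 that keep the pairs, a share of 0.0625, so chance cannot be excluded there. The highest other in both sets was 189, above the real 158, from the exchange of the diets in shGAL whole, again a structure of the diet groups. The arrays of a group are called technical replicates, so no split speaks to chance between animals.

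For the EGR2 difference, the lists that passed with the preset correlation were endothelial markers (median -1.05), matrix (-0.84), matrix proteases and inhibitors (-0.54), macrophage markers (-0.16), axon guidance (-0.11), lipid synthesis (0.44), oxidative phosphorylation (0.18) and interferon response (0.1), and lipid synthesis alone also passed with an estimated correlation. For the GAL difference they were lipid synthesis (0.47), inflammatory genes (0.3), endoplasmic reticulum stress (0.16), oxidative phosphorylation (0.13), interferon response (median 0, mean 0.29), axon guidance (-0.05), immediate early genes (-0.08) and synapse genes (-0.17), and again lipid synthesis alone also passed with an estimated correlation.

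Genes called in opposite directions by the diet with PLKO and with another hairpin, and called for the difference too, numbered 17 with shEGR2_40.9, 49 with shEGR2_38.9 and 5 with shGAL, where 5.88, 16.9 and 1.55 opposite ones would be expected from the counts alone. Genes called in the direction of PLKO were 5 higher and 21 lower with shEGR2_40.9 (1.64 and 5.01 expected), 11 and 13 with shEGR2_38.9 (6.09 and 7.97 expected), and 2 and 7 with shGAL (0.587 and 0.584 expected). Both kinds thus lay above the expected counts, and only with shEGR2_38.9 did the opposite ones outnumber the others. All these pairs of diet effects come from separate arrays, but from the same fit, which shares the spread of each gene between comparisons. Genes with little spread are more readily called in both, which can raise both kinds of overlap. The excess over the expected counts was not tested. The 5 opposite ones with shGAL were Cpe, Dennd1b, Fdps, Ifih1 and Peg3, each lower with the diet in PLKO and higher in shGAL. Fdps, an enzyme of isoprenoid and sterol synthesis, was the gene found with every hairpin, and it changed by -0.33 with PLKO (adjusted p = 0.027), 0.63 with shEGR2_40.9, 0.53 with shEGR2_38.9 and 0.53 with shGAL. The circadian gene Per2 changed by -0.73 with PLKO, 0.66 with shEGR2_40.9 and 0.47 with shEGR2_38.9, and Nr1d2 by 0.47, -0.60 and -0.38. Of the 49 genes with shEGR2_38.9, 41 were lower with the diet in PLKO and higher in shEGR2_38.9, among them the epidermal barrier genes Sdr9c7 (-0.76 and 1.83) and Alox12b (-0.82 and 1.45). These genes, apart from those the rule named, were chosen after their values were seen.

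The endothelial part of the EGR2 difference came with high control-diet levels: every shEGR2 array on the control diet lay at 0.72 or above for the list, and every other array at -0.05 or below. A lower share of epithelial cells would raise the other cell types alike only if their genes responded equally on the array. The endothelial list exceeded the Schwann and glial list by 1.41 (SE 0.17) in its shift against PLKO. Of the other 8 cell type lists, the pericyte and smooth muscle list came nearest, with a gap of 0.79 (SE 0.11), and the keratinocyte list lay furthest, with 1.46 (SE 0.21). The means of the pericyte (0.52, SE 0.08), macrophage (0.31, SE 0.07), adipocyte (0.3, SE 0.06) and fibroblast (0.21, SE 0.06) lists shifted up too. The Schwann and glial list shifted by -0.1 (SE 0.03) and the keratinocyte list by -0.15 (SE 0.1). The median over members was -0.06 for the macrophage and -0.03 for the adipocyte list, so their means rest on a part of the members. Between arrays of a shared batch, the fibroblast medians were 0.12 with shEGR2_40.9 and -0.23 with shEGR2_38.9. The lists thus did not shift alike. Genes near the array background or near the top of its range move less for the same change in share, and the lists were not matched for level. The gap therefore does not decide on a lower epithelial share, which stays open. The scan batch is argued against, since the list median was 1.34 and 1.67 between arrays of a shared batch. Endothelial cells may have been carried along to a different extent in each preparation, and this stays open, because the replicates are called technical and a group may be a single preparation; the largest range within a group was 0.64. A response of the stroma to EGR2 loss in the tumour cells stays open as well and was not tested, and the 15 endothelial markers include genes that other stromal cells also express.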

How the results depend on the processing

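No test in this part was chosen after the results were seen. Of 867 calls of named genes, 617 held in every alternative that kept all arrays, 584 held with each array left out in turn, 537 held in both, and 0 reversed. Calls lost were 76 with the scan batch as a block, 37 with no filter on dim probe sets, 44 with the mean of all probe sets, 181 with only the arrays compared, 18 with trend and robust options and 32 after renewed quantile normalization, and 0 of the 750 that remained with the filter at the 60th percentile. Of 17 results for Egr2 and Gal that missed the threshold, 3 passed in some alternative, all for Egr2. They were 0.33 for the diet with shEGR2_40.9 (adjusted p from 0.00295 without shEGR2_38.9 control-diet replicate 3 to 0.05 without replicate 2), -0.34 for the diet with shEGR2_38.9 without control-diet replicate 1 (adjusted p = 0.0277; without replicate 3 the change was -0.04, adjusted p = 0.799), and 0.34 for the EGR2 difference (adjusted p = 0.0118 with the mean of probe sets, adjusted p = 0.0144 without shEGR2_38.9 control-diet replicate 3).

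With only the arrays compared, the count was 70 in place of 140 for the diet with PLKO, 1295 in place of 2623 with shEGR2_38.9, 47 in place of 230 with shGAL, 105 in place of 158 for the GAL difference, 595 in place of 132 for EGR2 on the PA-rich diet, 1550 in place of 2987 for EGR2 and 1202 in place of 2013 for GAL on the control diet. That setting has fewer arrays, and its spread is not shared with the other groups. Fewer arrays alone would not be expected to raise a count, as for EGR2 on the PA-rich diet. The standard deviation of an array from its fellow arrays ran from 0.113 to 0.163 on the PA-rich diet and from 0.146 to 0.32 on the control diet. A spread shared by all groups is thus wide for PA-rich arrays and narrow for most control-diet arrays. P-values between control-diet groups may therefore be too small. With the mean of all probe sets the count was 386 for the diet with shGAL and 202 for EGR2 on the PA-rich diet. With the scan batch as a block it was 71 for EGR2 on the PA-rich diet. The causes of these moves were not tested. Every other count with all arrays stayed within 1.5 times its value.

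Leaving out each array in turn gave 56 to 269 genes for the diet with PLKO, 689 to 1534 with shEGR2_40.9, 1916 to 3225 with shEGR2_38.9 and 59 to 528 with shGAL. It gave 771 to 1603 for the EGR2 difference, 82 to 343 for the GAL difference, 59 to 257 and 2053 to 3327 for EGR2 on the PA-rich and control diets, and 968 to 2097 and 1432 to 2801 for GAL. Moves above 1.5 times were these. Without shEGR2_38.9 control-diet replicate 3 the count was 269 for the diet with PLKO, 528 with shGAL, 343 for the GAL difference and 257 for EGR2 on the PA-rich diet, although only the last of these uses its hairpin; leaving it out changes the spread that the model shares between groups. For the diet with PLKO the count was 80 and 88 without PLKO control-diet replicates 1 and 2, and 56, 77 and 88 without PA-rich replicates 1, 2 and 3. With shEGR2_40.9 it was 689 and 691 without PA-rich replicates 2 and 3. With shGAL it was 59 and 442 without control-diet replicates 2 and 3, and 121 and 75 without PA-rich replicates 2 and 3. For the GAL difference it was 85 without PLKO PA-rich replicate 1, 90, 82 and 317 without shGAL control-diet replicates 1, 2 and 3, and 93 without shGAL PA-rich replicate 3. For EGR2 on the PA-rich diet it was 59, 69 and 62 without PLKO PA-rich replicates 1, 2 and 3, 87 and 82 without shEGR2_40.9 replicates 2 and 3, and 85 and 87 without shEGR2_38.9 replicates 2 and 3. For GAL on the PA-rich diet it was 968 without PLKO PA-rich replicate 3. A group with an array left out has fewer arrays; beyond that the cause was not tested.

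Of 70 list calls, 11 held with an estimated correlation, 59 with fry, 65 with the scan batch as a block and 64 with no filter on dim probe sets, and 0 reversed. The calls lost with no filter were the interferon list for the diet with shEGR2_40.9 (adjusted p = 0.0811) and in the EGR2 difference (adjusted p = 0.0566), macrophage markers for the diet with shEGR2_38.9 (adjusted p = 0.283) and in the EGR2 difference (adjusted p = 0.3), and axon guidance (adjusted p = 0.151) and immediate early genes (adjusted p = 0.0791) in the GAL difference. Genes near 6.27 on the log2 scale lie close to the array background, which limits how small a fold can be seen for them. The alternative with another background correction was not run.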

Other observations

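The lymphatic, clock and RNA quality tests and the splits of whole groups in this part were chosen after the results were seen. The keratin genes Krt14 and Krt5 lay between 13.14 and 13.22 and between 12.77 and 13 in the 8 group means, and the Schwann cell transcription factor gene Sox10 between 7.44 and 7.57. These 3 genes were chosen after their values were seen, and levels of different probe sets are not on a common scale of transcript number.

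Because Prox1, Flt4 and Reln stood among the largest diet effects, lymphatic and blood vessel endothelium were compared with lists made afterwards. Of 10 lymphatic genes measured, 9 were higher with the EGR2 hairpins than with PLKO on the control diet (median 1.41), 8 fell with the diet with shEGR2_40.9 (median -1.72) and 9 with shEGR2_38.9 (median -1.71). With PLKO 1 fell (median -0.52), and with shGAL on the control diet 5 were lower than with PLKO (median -0.53). Of 7 blood vessel genes 5 were higher and 1 lower with the EGR2 hairpins on the control diet (median 0.76). The hypothesis that lymphatic genes moved further than blood vessel genes may rest on the genes that prompted it. With all members the lists differed by 0.44 (exact permutation test over 84 splits, two-sided p = 0.0476), but without the genes already named, leaving 7 and 6, they differed by 0.12 (exact permutation p = 0.429), with shifts of 0.93 (SE 0.18) and 0.81 (SE 0.13). The first comparison includes the genes that prompted it and the second leaves out genes that were called, so neither decides, and the hypothesis stays open.

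The opposite changes of Per2 and Nr1d2 with the diet in PLKO could come from a different time of day at collection. That would move other clock genes alike, but Tef, Hlf, Ciart, Per3 and Per1, 5 of 6 measured and well above the dim level, had a median absolute change of 0.14. This argues against it for the diet effect with PLKO only. Hlf was called elsewhere, at 0.43 for the diet with shEGR2_40.9 (adjusted p = 0.00479) and 0.55 for the EGR2 difference (adjusted p = 0.00354). Against PLKO on the control diet it was lower with the EGR2 hairpins (-0.46) and with shGAL (-0.58). Tef, Ciart, Per3 and Per1 were called in none of these comparisons. Time of day was not tested for them. No biological explanation was tested.

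Replicate 3 of shEGR2_38.9 on the control diet lay far from its group, with a standard deviation of 0.32 from its fellow arrays, against 0.113 to 0.215 in the other 23. A wrong label is argued against, since its mean correlation with its own group was 0.9784 and the highest with another group was 0.9725, with the lowest single value in its own group (0.9782) above the highest in the other (0.9739). Lower RNA quality is consistent with its Gapdh end difference of 0.76, outside the range of -0.12 to 0.08 in the other arrays. A different cell mix in this sample stays open: its deviations correlated by 0.09 between 2 probe sets of a gene over 4532 genes, against 0.11 to 0.34 elsewhere, lower by less than the standard deviation of 0.06 between arrays.

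For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. For the 4 diet effects, the real counts were 140, 1060, 2623 and 230 with PLKO, shEGR2_40.9, shEGR2_38.9 and shGAL, and the highest of the other splits were 0, 0, 1 and 1, or 0, 0, 1 and 0 among the splits that part all 3 pairs. The other splits keep some diet pairs together. For shGAL against PLKO the real counts were 1465 on the PA-rich and 2013 on the control diet, and the highest other was 1 in each case. For the EGR2 hairpins against PLKO, 1 of 100 drawn splits was as large on the control diet and 2 on the PA-rich diet, the real one included. On the control diet this excludes chance in the grouping of single arrays only. The drawn splits mix arrays of different groups, and the median count of the others was 0. They therefore do not exclude chance between whole groups. Since the arrays of a group are called technical replicates, chance between animals is not excluded. On the PA-rich diet the real count was 132 and the highest other 587. That split set the 3 shEGR2_40.9 arrays against the rest, with PLKO and shEGR2_38.9 arrays mixed within the remaining groups. On the control diet the real count was 2987 and the highest other 2514. That split set the 3 shEGR2_38.9 arrays against the rest, with PLKO and shEGR2_40.9 arrays mixed within the remaining groups. The draw did not hold the splits that exchange a whole group with PLKO and leave every group unmixed. With shEGR2_40.9 or shEGR2_38.9 against the rest these gave 680 and 287 on the PA-rich diet, above the real count, and 562 and 2979 on the control diet, the last near the real count. This points to the structure of the 3 groups. On the PA-rich diet the real count was the lowest of the 3 splits into whole groups, so it does not set PLKO apart from both EGR2 hairpins.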
